A study of Mus musculus with 6 samples.

How the data were processed

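RNA sequencing was done on polyA RNA of epithelial cells enriched from mammary tumors of 6 female mice of 7 weeks, 3 labelled PyMT control and 3 labelled PyMT Elp3 cKO. Per the labels' protocols, tumors of similar size were dissociated, epithelial cells were selected with an enrichment kit, and libraries were made with a kit that the protocol does not describe as keeping strand, so overlapping genes on opposite strands cannot be told apart. Per the submitters' processing notes, TopHat2 2.0.9, Cufflinks 2.1.1 and Cuffdiff were used with the mm10 build. The role of each tool, the annotation and any filter are not given in the sources used here.

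The authors deposited 1 table of the whole series, read here as a text copy of a workbook sheet that was not itself examined, with FPKM per gene for 6 columns named by genotype and number and a further column headed as a total of FPKM. FPKM values are scaled by the authors to gene length and library size, and how libraries were scaled against each other is not given in the sources used here. Columns were matched to samples by name, and 0 columns of values were left without a match. The further column was treated as the authors' deposited summary over several values and given no sample. Rows without a gene symbol (1366 rows) held 11.9%, 10.0% and 7.84% of summed FPKM in profiles 1, 2 and 3. They stayed in totals and in the identity check and out of gene results. Another 514 rows name several genes, and 332 symbols are on more than 1 row, where the row with the higher mean was used. Row positions are as deposited, with starts raised by 1. This was checked on 19917 symbols found in the RefSeq GRCm38.p6 table, of which 41.8% have the deposited start 1 below the RefSeq start and 2.65% have an equal start.

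Before the data were examined, the plan was a limma fit of log2(FPKM + 1) between genotypes with an adjusted p threshold of 0.05, set tests on 31 gene lists and an exact permutation test for Elp3. The files were then compared column by column. Same-numbered control and Elp3 cKO columns are identical in all rows, so these tests were not run. The unpaired fit would return a difference of 0 for every gene, and the paired fit has no residual spread. What was computed instead is descriptive: values per profile, medians and ranges over the 3 distinct profiles, the number of list genes with a mean of 1 FPKM or more, and ranges on log2(FPKM + 1), a scale that understates changes of low genes. The lists held 671 entries, of which 619 were measured, 31 stood only in rows naming several genes and 21 were in no row. Lists overlap in some genes. Genes were named by the rule fixed in advance: Elp3, Lef1, Dek, the other Elongator subunits and members of each list. Since no test was run, these were the 2 members of each list with the highest mean. Some genes that this rule takes are not reported here. Other genes named (Esr1, Pgr, Acta2, Smr3a, Bpifa2, Irs2 and those in the closing section) were chosen after their values were seen.

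The authors' summary column was examined by arithmetic. Times 9, it ended at 4 decimals (within 1e-07) in 91.4% of 5957 rows with values from 10 to 1000, against at most 30.3% for any other multiplier from 2 to 12. From 9 times the summary, the 3 profiles were subtracted 2 times, with a relative tolerance of 1e-09 for a remainder of 0. The procedure was tested on simulated data of 24308 rows. With 3 libraries entered 2 times plus 3 others, 0 rows came out below 0 and 403 exactly at 0, and with 9 separate libraries 633 rows came out below 0 and 0 exactly at 0. Alternatives were median-ratio scaling, quantile normalization, other minimum levels, a wider tolerance and leaving out each replicate number. Computation used Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. The files give no counts, so depth sets no interval here, and the number of distinct profiles limits the precision.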

Results

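The series set mammary tumor epithelial cells from PyMT mice, which carry the polyoma middle T oncogene, against cells from PyMT mice in which Elp3 was deleted with MMTV-Cre. Elp3 is the catalytic subunit of Elongator, a complex that modifies wobble uridines in tRNA. The labels give 3 control and 3 Elp3 cKO tumors, each from a different 7-week-old female FVBN mouse and matched for size. PolyA RNA of the enriched epithelial cells was sequenced, and gene levels were deposited as FPKM (fragments per kilobase of transcript, scaled to library size). The deposited table holds 24308 rows, of which 1366 have no gene symbol.

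The table, in the text copy read here, does not hold separate values for the 2 genotypes. Elp3 cKO column 1 was equal to control column 1 in every row, and the same held for the columns numbered 2 and 3, with 0 of 24308 rows differing in each case. Columns of different number shared no value above 0: control 1 and Elp3 cKO 2 differed in 17606 of the 17606 rows in which either was above 0. The 6 columns are therefore 3 distinct profiles, each carrying both labels, and they are called profiles 1, 2 and 3 by their replicate number. Each was counted once, and no profile was assigned to a genotype. The difference of group means is 0 in every row by construction, so it is no measurement of the effect of Elp3 loss, and no test between genotypes was made. Values are given per profile, or as a median with the range over the 3 profiles, without a mean and SD, because the labels do not place the profiles in 1 group.

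**Figure D1:**
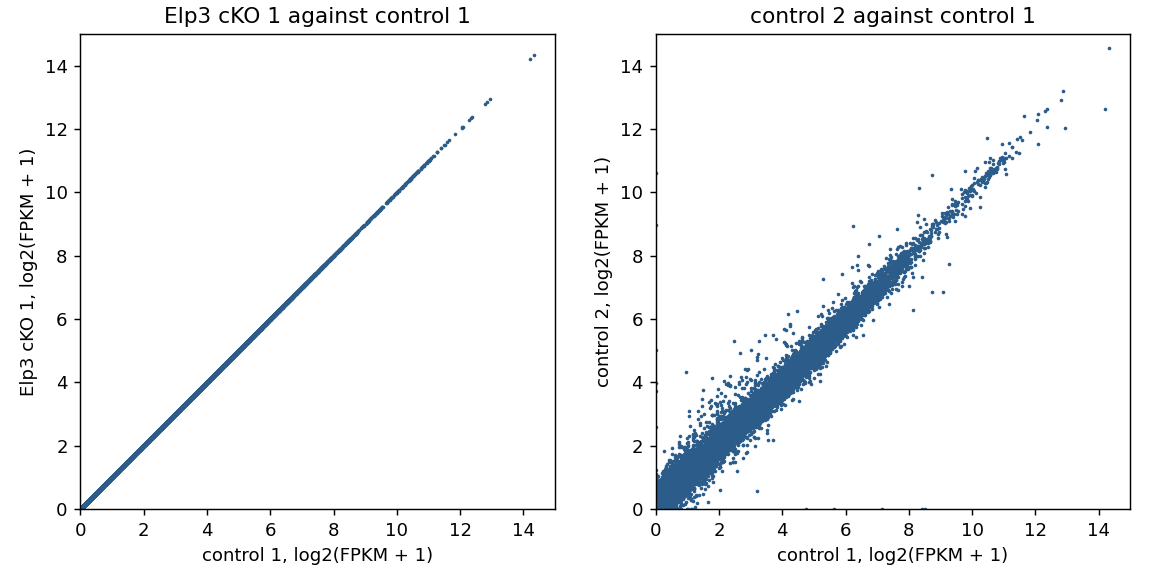
Each point is a row of the table, with axes in log2(FPKM + 1). In the left panel Elp3 cKO 1 is plotted against control 1 and all 24308 rows lie on the diagonal. In the right panel control 2 is plotted against control 1 and the rows scatter.

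The 3 profiles were of similar breadth. FPKM summed to 622789 in profile 1, 636842 in profile 2 and 621793 in profile 3, and 11380, 11569 and 11527 rows stood at 1 FPKM or more. Across the 11557 rows with a mean of 1 FPKM or more, Pearson's r of log2(FPKM + 1) was 0.98 between profiles 1 and 2, 0.97 between profiles 1 and 3, and 0.97 between profiles 2 and 3. These correlations run across genes, which are not independent replicates. Absolute depth is unknown from these values, so no counting intervals are given. Relative depth may show in part. Among rows under 0.15 FPKM, 25.8% of the ratios of profile 2 to profile 3 fell in a single step at 1.17. Whole fragments of fixed worth could give such a step, which was not tested. For profile 1 over profile 2 the commonest step held 2.79% of rows, and for profile 1 over profile 3 it held 3.12%.

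Elp3 was expressed in all 3 profiles, at 15.6, 17.9 and 19.0 FPKM. Its row covers chromosome 14, 65530446 to 65593112 (mm10), the whole gene, so the value sums over all exons and would not resolve loss of single exons. Other Elongator subunits were expressed too. Elp5, listed as Rai12, had a median of 34.3 FPKM (range 30.9 to 39.9) and Elp2 had 32.4 (29.0 to 33.2). Elp4 had 5.32 FPKM (5.11 to 5.94). Elp6 was matched to no row. The 12 genes listed for wobble uridine modification of tRNA beyond Elongator were all at 1 FPKM or more. Their list median was 8.41 (range over profiles 8.03 to 9.66). Trmt112, which activates several tRNA methyltransferases, led them at 60.9 FPKM (58.2 to 62.5). Kti12, an Elongator cofactor, stood at 19.1 (18.5 to 28.3).

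Lef1, the Wnt transcription factor named in the study's title, was listed at 0 in profiles 1 and 2 and at 0.0216 FPKM in profile 3. Its row spans chromosome 3, 131110471 to 131223331. Dek, which encodes a chromatin and RNA-binding protein, was well expressed, at 34.9, 35.3 and 35.4 FPKM. Dek has 2 rows at chromosome 13, 47043499 to 47106221, a locus shared with Kdm1b, and the other stood at 0.859 FPKM (0.766 to 1.37). Of 25 measured Wnt and LEF1/TCF target genes, 10 were at 1 FPKM or more, and the list median was 0.683 (0.569 to 0.766). The members with the highest means were Myc, at 99.2 FPKM (97.0 to 130), and the adhesion receptor Cd44, at 86.3 (84.8 to 95.2).

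Luminal keratins were among the most abundant transcripts. Krt18 and Krt8, the keratin pair of simple epithelium, reached medians of 4959 FPKM (4232 to 5010) and 3231 FPKM (3060 to 3285), ranks 5 and 8 among rows naming a single gene other than small RNAs. Of 22 luminal and hormone-sensing genes, 19 were at 1 FPKM or more and 9 at 100 or more. Within that list the hormone receptors were low: Esr1, the estrogen receptor, had 1.07 FPKM (0.896 to 1.17) and Pgr, the progesterone receptor, 3.17 (1.57 to 3.58). Luminal progenitor and alveolar genes were nearly all detected, 15 of 16 at 1 FPKM or more, with the iron-siderophore binder Lcn2 at 3439 FPKM (2913 to 4169) and the lipid droplet coat protein Plin2 at 1116 (982 to 1300). All 9 milk protein genes were at 1 FPKM or more on average, and each was highest in profile 3, the profile that also carried the salivary secretory gene Smr3a at 561 FPKM against under 1 in the others. Their list median was 55.4 FPKM in profile 1, 40.7 in profile 2 and 162 in profile 3. Csn3, kappa-casein, stood at 1363, 1145 and 2415 FPKM, and Csn2, beta-casein, at 428, 115 and 1025.

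Basal keratins were present below the luminal ones. Krt14 had 239 FPKM (215 to 320) and Krt17 had 204 (194 to 215), while the list median over 18 basal and myoepithelial genes was 5.69 (3.46 to 6.15). Acta2, smooth muscle actin, stood at 18.5, 34.3 and 74.0 FPKM. Of 25 invasion and mesenchymal genes, 23 were at 1 FPKM or more and 20 were lowest in profile 1. The list median was 6.38 FPKM in profile 1, 16.0 in profile 2 and 17.9 in profile 3. The matrix metalloproteinase Mmp3 stood at 74.6, 488 and 114 FPKM. Of the fibroblast and matrix genes, all 19 were lowest in profile 1 as well, and the list median was 2.98, 8.73 and 9.00. The share of all rows lowest in profile 1 is not given here, so these counts are not read as particular to these lists. Gsn, gelsolin, had 96.3 FPKM (91.1 to 101), and Dcn, the matrix proteoglycan decorin, stood at 18.2, 54.4 and 66.8.

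Markers of most other cell types were low, in cells enriched for epithelium. Endothelial genes had a list median of 2.22 FPKM (1.90 to 4.39), with Emcn at 9.25 (3.50 to 9.95) and Cdh5 at 7.50 (3.72 to 8.43). Of 21 macrophage and myeloid genes, 6 were at 1 FPKM or more, and the median was 0.418 (0.259 to 0.510). The members with the highest means were S100a8, a calprotectin subunit, at 71.6 FPKM (43.6 to 98.8), and the lipopolysaccharide co-receptor Cd14, at 55.2 (49.9 to 102), which was also on the luminal progenitor list. None of 18 lymphocyte genes reached 1 FPKM, and 9 were listed at 0 in all profiles; the highest were Lck, at 0.311 (0.295 to 0.363), and Cd79a, at 0.1001 (0.0857 to 0.166). The adipocyte median was 0.155 (0.0568 to 0.176), with Lpl at 3.36 (2.86 to 4.404) and Slc2a4 at 1.46 (1.44 to 1.54). Skeletal muscle genes had a median of 0.0465 (0 to 0.0680), with Mb at 3.77 (3.60 to 4.14) and Acta1 at 0.745 (0.687 to 0.902). The 3 erythroid genes measured had a median of 0.0131 (0 to 0.0228), Alas2 standing at 0.0994 and Slc4a1 at 0.0131. The peripheral nerve list had a median of 1.38 (1.36 to 1.48), but Sox10, a transcription factor of neural crest that mammary epithelium also expresses, reached 86.6 FPKM (77.0 to 102), and Mbp 21.3 (20.8 to 21.7).

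**Figure D2:**
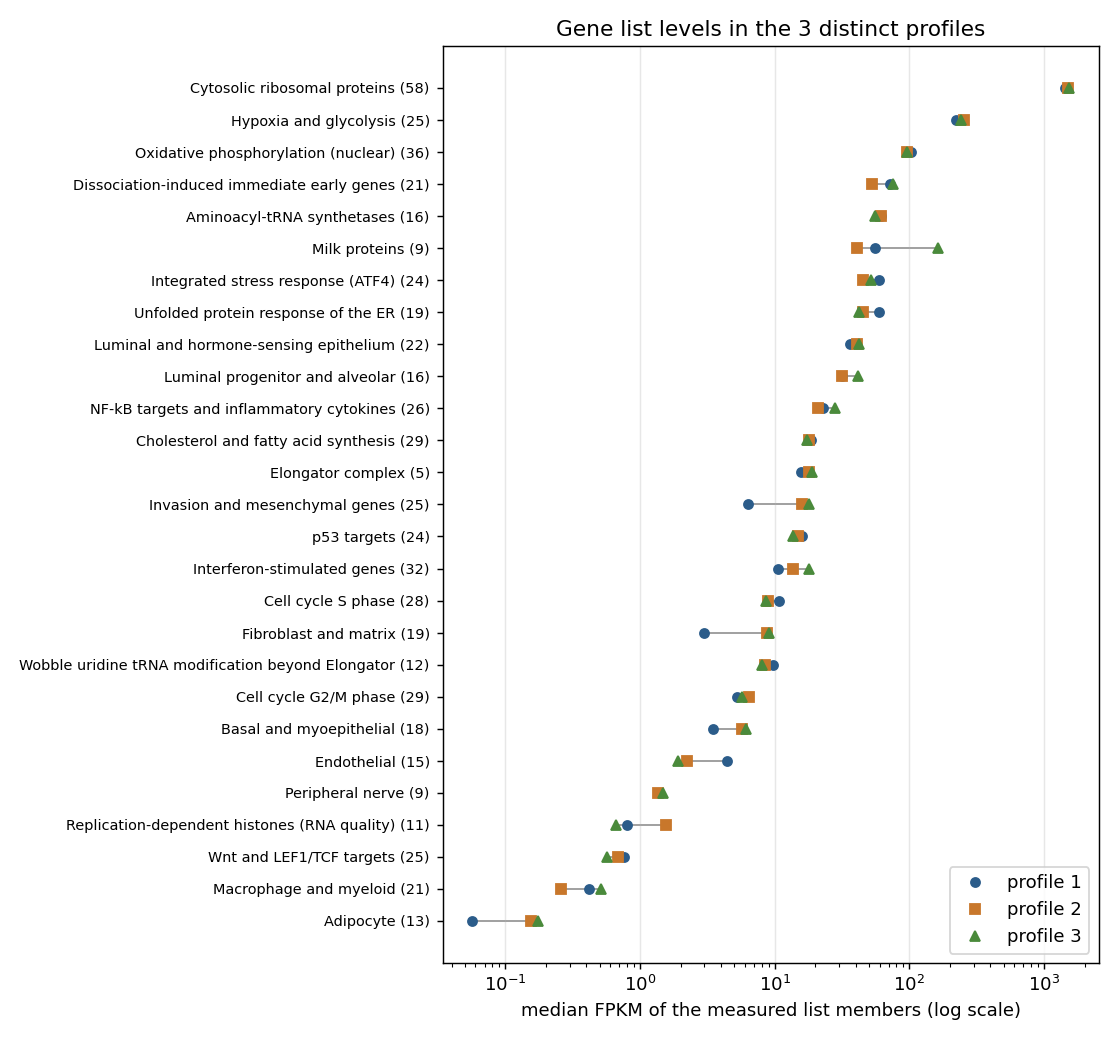
Median FPKM (log scale) of the measured members of each gene list, one marker per distinct profile, the line joining the lowest and highest; the number measured is in brackets and lists with a profile at 0 are left out. Ribosomal proteins lie highest at a median of 1498 FPKM, and the milk protein, adipocyte, fibroblast and invasion lists have the longest lines among those drawn.

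Glycolytic and translation genes were abundant. The 25 hypoxia and glycolysis genes had a median of 240 FPKM (220 to 254), led by Gapdh at 2987 (2714 to 3328) and Aldoa at 2081 (2016 to 2440). The 58 cytosolic ribosomal protein genes had a median of 1498 FPKM (1431 to 1523), led by Rplp1 at 2493 (2420 to 2865) and Rps2 at 2494 (2431 to 2692). For 36 nuclear genes of oxidative phosphorylation the median was 96.1 (95.9 to 103), with Atp5b at 662 (662 to 679) and Cox4i1 at 424 (414 to 430). The 16 aminoacyl-tRNA synthetases, which charge tRNAs, had a median of 61.5 (55.1 to 62.0), led by Nars at 222 (202 to 266) and Gars at 113 (111 to 147). Cholesterol and fatty acid synthesis genes had a median of 18.0 (17.3 to 18.7); Fdps stood at 59.9 (56.2 to 63.8), and Scd1, a fatty acid desaturase, at 75.3, 131 and 174.

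Stress and signalling genes were expressed in every profile. All 24 genes of the integrated stress response were at 1 FPKM or more, with a median of 52.0 (44.9 to 59.9). Ddit4, an mTOR inhibitor, had 334 (262 to 434) and Atf4, the pathway's transcription factor, 322 (270 to 354). The unfolded protein response list had a median of 45.4 (42.6 to 59.0), with the ER chaperones Hspa5 at 742 (605 to 883) and Hsp90b1 at 453 (405 to 480). For p53 targets the median was 14.8 (13.7 to 15.9), Plk2 standing at 253 (249 to 257) and the cell cycle inhibitor Cdkn1a at 218 (196 to 219). All 32 interferon-stimulated genes were at 1 FPKM or more, 28 of them highest in profile 3, and the median was 10.5, 13.7 and 17.9 FPKM in profiles 1, 2 and 3. Also highest in profile 3, which carried the salivary genes Smr3a and Bpifa2, were 20 of 26 NF-kB and cytokine genes and 15 of 21 macrophage and myeloid genes. The same held for 13 of 16 luminal progenitor and 18 of 25 invasion genes, but for 1 of 29 G2/M and 1 of 25 hypoxia genes. Counts were also low for endothelial (1 of 15), S phase (4 of 28) and unfolded protein response genes (4 of 19). They were 0 of 16 for aminoacyl-tRNA synthetases and 0 of 12 for wobble uridine genes beyond Elongator. Of the 21 myeloid genes only 6 were at 1 FPKM or more. The share over all rows is not given here, and no link to the salivary genes was tested. Bst2, tetherin, stood at 106, 160 and 256 FPKM, and Isg15, a ubiquitin-like modifier, at 41.6, 44.7 and 84.4. The NF-kB and cytokine list had a median of 22.9 (21.0 to 27.8), with the inhibitor Nfkbia at 173 (150 to 223) and the chemokine Cxcl1 at 142 (117 to 254).

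Proliferation genes were detected throughout. The 28 S phase genes had a median of 8.98 FPKM (8.605 to 10.8), with Pcna at 99.1 (93.8 to 105) and Mcm7 at 31.0 (29.8 to 33.7). The 29 G2/M genes had a median of 5.71 (5.27 to 6.45), led by Ube2c at 41.3 (33.1 to 44.0) and the cytokinesis protein Anln at 20.5 (18.3 to 24.7). A pair of preset lists was meant to read the handling of the cells and RNA. Without samples handled otherwise, their levels cannot be told apart from baseline expression. Immediate early and heat shock genes, which rise during tissue dissociation, had a median of 72.1 (52.7 to 75.3), with Hspb1 at 2467 (2220 to 2751) and Ier3 at 749 (681 to 792). Replication-dependent histones, most of which lack polyA tails, had a median of 0.799 (0.658 to 1.56); Hist1h2bc stood at 75.2 (72.8 to 141) and Hist1h1c at 82.0 (76.9 to 111). The 13 mitochondrially encoded genes were matched to no row.

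Most genes differed little between the profiles. Of 8015 rows naming a single gene, other than small RNAs and predicted genes, with a mean of 5 FPKM or more, 232 spanned 1 or more on the log2(FPKM + 1) scale, and the median span was 0.25. With a single profile per replicate number there is no test of these spreads. Smr3a and the genes in the next 2 sentences were chosen after their values were seen. The widest span belonged to Smr3a, a salivary secretory gene, at 0.615, 0.239 and 561 FPKM, followed by Bpifa2 at 0.0697, 0.442 and 177. Irs2, an insulin receptor substrate, stood at 0.955, 19.0 and 19.96 FPKM, profile 1 being the low one. Its locus holds 2 other rows, and how reads were divided among them is not known.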

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

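All tests in this part were chosen after the identical columns had been seen. The median ratio over further salivary markers was set after salivary genes had been seen in profile 3, but before those further markers were looked at. A signal stood outside the sample columns: 1007 rows were listed at 0 in all 6 of them while the authors' summary column was above 0. These values were mostly small, with a median of 0.0055 FPKM in the summary, and 3 rows reached 1, the highest being the small nucleolar RNA Snora30 at 145. The arithmetic of the summary matches a mean over 9 values, which leaves 3 values per row that the table does not show.

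The identical columns were weighed against 3 accounts. Entry of 1 set of libraries 2 times in the table predicts equality to the last digit, and 0 rows differed between same-numbered columns. That equality is the observation that raised the question, so it is no separate support. Separate libraries of 2 genotypes with no difference would carry sampling noise, yet at least 16816 rows above 0 were equal to the last digit between same-numbered columns and 0 between different-numbered ones, which argues against it. A copy made only after the summary column was computed would leave some rows below 0 when both copies are taken from 9 times the summary. No row was below 0 and 439 were exactly 0, so the tables argue against that too, unless the summary was recomputed later. The equality is that of the text copy read here, and the workbook itself was not examined. Equality made when the workbook was converted would also come after the summary, so the 439 rows argue against it, with the same exception. Which genotype the 3 profiles came from stays open.

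Profile 3 carried salivary secretory genes: Smr3a stood at 0.615, 0.239 and 561 FPKM in profiles 1, 2 and 3, Bpifa2 at 0.0697, 0.442 and 177, Chia at 0, 0 and 119, and the row naming Amy1 (salivary amylase) and Rnpc3 at 9.33, 9.48 and 210. Salivary tissue in the tumor sample, which a selection for epithelial cells need not remove, may be the source, but of 16 further salivary markers 14 were in the table, and over the 10 of them above 0.1 FPKM in any profile the median ratio of profile 3 to the higher of the others was 1.05, under the bound of 1.5 set beforehand as counting against it. That bound was poorly chosen, as became clear only after the result: 5 of the 10 (among them Aqp5, Lpo, Pip and Bhlha15) were already at 1 FPKM or more in profile 1 or 2, where a small admixture would not show, and of the 9 under 1 FPKM there, 3 were listed at 13.4 (Dnase1), 2.05 (Klk1) and 1.34 FPKM (Prpmp5) in profile 3 against at most 0.649 in the others. The other 6 lend salivary tissue no support. Egf and Lman1l were not higher in profile 3, and 4 (Smr2, Prh1, Dcpp3 and Klk1b22) were listed at 0 in all profiles. Whether these 6 would be expected in salivary glands of female mice was not examined. Dcpp3 differed from Dcpp1 and Dcpp2, which had been seen before this test. With Cst10, also seen before, they stood at 93.4, 17.8 and 19.4 FPKM in profile 3, against at most 0.215 in the others. The source stays open, since the further markers were divided and no explanation other than admixture was tested. Abpa, another gene of glandular secretions, was lowest in profile 3 (37.8, 154 and 2.58 FPKM). So were Abpb (81.7, 210 and 14.6 FPKM) and Prol1, both picked after their values were seen. Genes of glandular secretions were thus not confined to profile 3. Admixture adds transcripts and does not remove them, so it would not by itself lower these genes. Whether salivary tissue would bring Abpa, Abpb or Prol1 was not examined, so no conclusion is drawn from their low levels in profile 3.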

How the results depend on the processing

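No paired analysis was possible because same-numbered columns of the 2 genotypes are identical, so every paired difference is 0 and no residual spread remains. Other settings fixed before the data were examined for the genotype test and the set tests (pseudocount, variance model, library weights, filter, fold threshold, estimated correlation, leaving out single libraries) were not run for the same reason: they would compare a set of values with itself or with a part of itself. For Elp3, the pseudocount, variance model and library weights do not act on a level in FPKM. The alternatives named next, other than those for Elp3, were added after seeing the data. The Elp3 median of 17.9 FPKM was 17.9 under median-ratio scaling and 18.1 under quantile normalization, both within 1 SD of the profiles, and lay between 16.7 and 18.5 without each replicate number, where a median of 3 values cannot move by 1 SD. The number of rows at a mean of 1 FPKM or more, 11557, was 8561 at a minimum of 5 FPKM, and it became 18033 when any value above 0 counted, since fewer rows were excluded. It lay between 11490 and 11580 under the scalings and without each replicate number. The 439 rows fully accounted for by 2 copies were 439 under the wider tolerance. Of 60 list medians recomputed under these scalings, 59 stayed within 1 SD of the profiles, the exception being the peripheral nerve list, at 1.46 in place of 1.38 FPKM under quantile normalization. Leaving out replicate numbers gave 90 list medians, of which 4 moved by more than 1.5 times: the milk protein median of 55.4 FPKM was 101 without replicate 1 and 109 without replicate 2, the skeletal muscle median of 0.0465 was 0.0232 without replicate 3, and the erythroid median of 0.0131 was 0.00654 without replicate 1. Low genes are limited by unknown depth: Lef1, at 0 in 2 profiles, can be read only as listed at 0 there.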

Other observations

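The remainder of the authors' summary, after both copies of the 3 profiles are taken out, corresponds to the mean of 3 values per gene that have no label. It cannot be placed in a genotype, tissue or study, has no spread, and was put to no test; the remainder divided by 3 is given here as a value beside the profiles, chosen after the data were seen. Among 11418 named rows at 1 FPKM or more in either, the remainder lay above all 3 profiles in 32.7% and below all 3 in 39.97%, and the median log2 ratio with a pseudocount of 1 was -0.05. Elp3 stood at 19.4 FPKM in the remainder, against 15.6 to 19.0 in the profiles, Dek at 41.1 against 34.9 to 35.4, and Lef1 at 0.0954 against 0 to 0.0216.

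These are the preset lists with at least 70% of their measured genes on one side of all 3 profiles in this remainder. The list counts take every measured gene, while the shares above cover only rows at 1 FPKM or more in either. Of the 21 macrophage and myeloid genes, only 6 had a mean of 1 FPKM or more over the profiles. Above lay 16 of 18 basal and myoepithelial genes, all 15 endothelial genes, 17 of 19 unfolded protein response genes and 7 of 9 peripheral nerve genes; Acta2 stood at 464 FPKM against 18.5 to 74.0, and Krt5, a basal keratin, at 418 against 59.2 to 78.7. Below lay all 29 measured G2/M genes, 26 of 28 S phase genes, 15 of 16 aminoacyl-tRNA synthetases, 29 of 32 interferon-stimulated genes, 47 of 58 cytosolic ribosomal protein genes, 7 of 9 milk protein genes and 15 of 21 macrophage and myeloid genes. Wap, a whey protein, stood at 0.166 FPKM against 40.7 to 162. Pgr, the progesterone receptor, stood at 42.7 against 1.57 to 3.58, Lcn2 at 547 against 2913 to 4169, and the cyclin Ccnd1 at 20.03 against 60.7 to 76.2. The coat color gene a, agouti, stood at 19.2 FPKM against 0 to 0.226 in the profiles.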
